A study of Homo sapiens with 12 samples.

How the data were processed

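RNA was sequenced from SEM, an established B cell precursor acute lymphoblastic leukaemia line, in 12 libraries. The labels cross genotype (wild type, WT, or IKZF1 knockout, KO) with treatment (untreated, or 1 µM cytarabine, AraC, for 16 hours), with 3 libraries in each of 4 groups. Per the labels' protocols, RNA was purified with a column kit and a service company did the sequencing and primary data analysis. The labels number the replicates 1 to 3 but do not say that they came from separate cultures, so p-values here measure the spread between these libraries, which may be technical. Library preparation, strandedness and read length are not given in the sources used here.

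The deposited values are FPKM (sequenced fragments scaled to gene length and library size) per gene, in 1 table of 58735 genes with all 12 libraries. The submitters' processing notes name fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3, with the builds hg38 and GRCh38; how each was run is not given in the sources used here. All 58735 identifiers and positions in the table matched GENCODE release 29 on GRCh38, and the coordinates printed are those of the table. The table also gives gene lengths, so multiplying FPKM by length returned whole reads: in every library 100% of values above 0 came within 0.001 reads of a whole number. The recovered totals were 16342979 to 22733932 reads assigned to genes per library. The library sizes implied by the deposited FPKM were not those totals: they followed median-of-ratios factors computed from the reads, with a spread of 0.511% between libraries. The FPKM therefore already carry the authors' scaling between libraries. The mean of the authors' factor was 0.957 in untreated WT, 1.07 in AraC-treated WT, 0.942 in untreated KO and 1.03 in AraC-treated KO libraries.

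The analysis used log2(FPKM + 0.5) for genes with FPKM of at least 1 in at least 3 of the 12 libraries, which left 13300 genes, 10434 of them protein-coding. All 12 libraries entered one limma model (3.58.1, in R 4.3.3) with a mean per group, a moderated variance with a trend over mean expression, and 8 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05; calls of at least 2-fold were counted as well. The 5 comparisons were AraC against untreated in WT and in KO, KO against WT without and with AraC, and the interaction, which is the AraC effect in KO minus that in WT. Fold changes on this scale understate the change of genes near the pseudocount.

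For 29 gene lists, written down before the data were examined, limma's camera test compared each list with all other tested genes at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 28 lists with at least 4 tested genes. Calls were repeated with an estimated correlation. The size of the AraC response in KO relative to WT was a total least squares slope over genes called for the average AraC effect, with a score per treated library compared by an exact two-sided permutation test; with 3 libraries against 3 its p cannot go below 0.10. Genes were named by a rule fixed before the data were examined. It takes, per comparison, the 10 most increased and 10 most decreased protein-coding genes past the threshold with a mean FPKM of at least 5 in the higher group and no overlap between the 2 groups (no such demand for the interaction). It adds up to 4 members of each list with the smallest adjusted p and a mean FPKM of at least 1, all Ikaros family members and all genes of the list on cytarabine transport and metabolism. A few genes that the rule names are not reported here.

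The procedure was tested on simulated reads for the 13300 genes with 100 genes changed 1.5-fold and 100 changed 2-fold. In the AraC comparison in WT it recovered 75% and 85% of them with 2.44% false among the calls, in the AraC comparison in KO 74% and 87% with 4.17% false, for KO against WT untreated 75% and 84% with 7.02% false, for KO against WT with AraC 72% and 87% with 5.36% false, and for the interaction 66% and 80% with 4.58% false. The false share of the 2 KO against WT comparisons thus lay over the threshold of 0.05. Each share comes from a single simulated draw, so whether the comparisons differ in it was not tested. Of the lists, 3 of 3 shifted by 1.3-fold were called in the AraC comparison in KO, and 0 others. All simulated genes varied independently of each other, at 1 shared dispersion of 0.0013 taken from genes with many reads. The list result therefore could not show false calls that come from correlation between genes. Recovery of genes with a larger spread was not tested. Before the data were examined, alternatives were fixed for the pseudocount, the filter, the scaling (TPM, median of ratios, quantile), the variance model, sample weights, limma-voom on the recovered reads, a replicate block, the libraries in the fit, the set test and leaving out each library. Scaling by plain read totals was added after seeing the data. Quantile normalization gives every library the same distribution of values. A median that it brings to about 0 therefore cannot tell an effect of scaling from a real joint change of genes with similarly high values. Figures were drawn with matplotlib 3.10.9. Counting intervals and floors of 3 reads per library cover counting error only, since the reads carry no molecular identifiers that are known here. Reads shared between near-identical genes, such as histones and ribosomal protein genes with pseudogenes, and between overlapping genes could not be resolved from the table.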

Results

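The series asks, by its title, how loss of IKZF1 relates to the response of B cell precursor leukaemia cells to cytarabine (AraC), a cytidine analogue that is incorporated into DNA and stalls replication. SEM carries a KMT2A-AFF1 fusion. Each of the 4 groups (untreated WT, AraC-treated WT, untreated KO and AraC-treated KO) held 3 libraries. WT AraC replicate 1 had 22733932 reads assigned to genes and the other 11 had 16342979 to 16913784. Between 12051 and 12646 genes reached an FPKM of 1 in a library. Mitochondrial transcripts took 2.55% to 2.99% of reads as group means. The leading principal component (32.5% of variance) separated treated from untreated libraries and the next (26.6%) separated KO-labelled from WT libraries. Replicates correlated at 0.979 to 0.984 and differed by more than sampling noise, with a chi-square per degree of freedom of 2.24 to 7.95. The 2 highest values, 6.43 and 7.95, were both pairs with KO AraC replicate 3.

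IKZF1 encodes Ikaros, a zinc finger transcription factor of lymphoid development, and lies on chromosome 7 from 50304068 to 50405101. Its FPKM was 22.1, 22.6 and 22.4 in the untreated WT libraries and 20.5, 21.5 and 21.3 in the untreated KO libraries. With AraC it was 14.2, 14.8 and 15.3 in WT and 14.2, 14.3 and 15 in KO. The KO against WT difference without AraC was -0.08 log2 (95% interval -0.16 to -0.00, limma, Benjamini-Hochberg adjusted p = 0.12). It passed at -0.10 under TPM, quantile normalization and plain read totals (limma adjusted p = 0.037, 0.037 and 0.026). A knockout made by a small frameshift or a short deletion can leave the RNA level as it was, so this gene total does not check the genotype labels. All directions below between KO and WT therefore rest on the labels, and the libraries are called KO-labelled. The labels name 1 knockout line, so differences between lines cannot be separated from the genotype.

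Among the other Ikaros family members, IKZF3 (Aiolos) was lower in the KO-labelled libraries, at 0.55 ± 0.05 against 1.18 ± 0.18 FPKM without AraC (SD, n = 3 each). Its log2 difference was -0.68 without and -0.89 with AraC. IKZF5 was lower by -0.56 and -0.39, and IKZF2 (Helios) was higher by 0.33 and 0.44. All 6 values passed limma's Benjamini-Hochberg threshold, with adjusted p from 0.00039 to 0.0075. IKZF4 differed by 0.17 and 0.25 and did not pass (adjusted p = 0.23 and 0.085). As a list of 5, the family was not shifted against other genes in any comparison, with medians from -0.28 to 0.07.

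**Figure D1:**
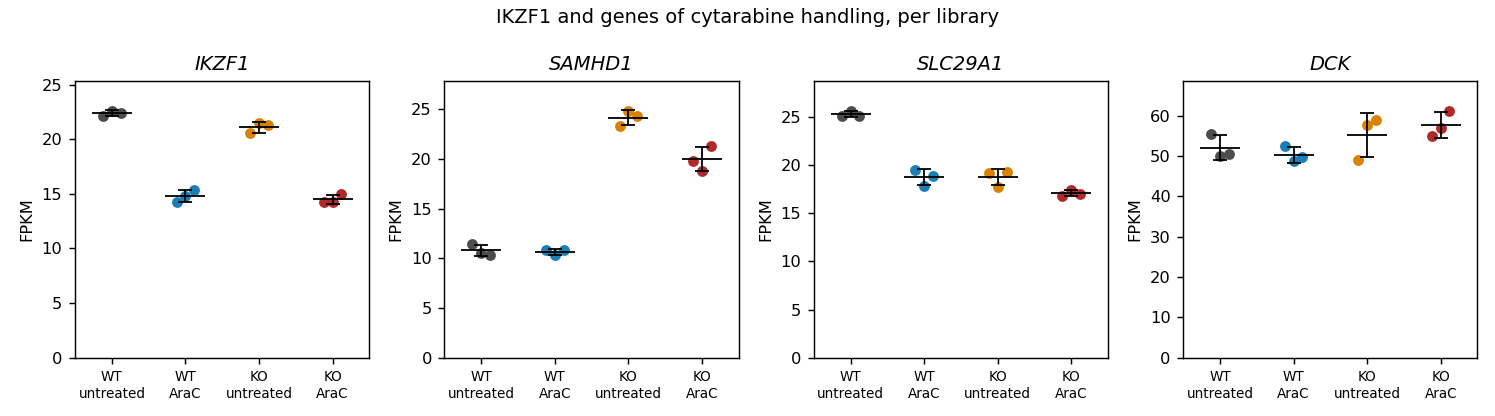
FPKM of IKZF1, SAMHD1, SLC29A1 and DCK in each of the 12 libraries (points), with group mean and SD (bars, n = 3), by genotype label and treatment. IKZF1 differed little between the genotypes and fell with AraC in both, while SAMHD1 was 10.8 in untreated WT and 24.1 in untreated KO-labelled libraries.

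In WT cells, 16 hours of AraC raised 18 of 29 tested genes of the integrated stress and unfolded protein response and lowered 28 of 39 mitotic genes. Both lists passed limma's camera test at a preset correlation and not with an estimated one (adjusted p = 0.17 and 0.16). TRIB3, a pseudokinase induced by ATF4, went from 2.40 ± 0.17 to 41.8 ± 2.62 FPKM (SD, n = 3 each, log2 fold 3.87 ± 0.08 SE). JUN went from 2.77 ± 0.18 to 28.9 ± 2.57 and ATF3 from 1.16 ± 0.31 to 12.2 ± 0.60 (log2 folds 3.17 and 2.95). The mitotic kinase PLK1 went from 29.4 ± 0.99 to 8.54 ± 0.27 and the mitotic kinesin KIF20A from 28.6 ± 0.51 to 8.27 ± 0.22 (-1.72 and -1.73). MYC, on chromosome 8 from 127735434 to 127741434, went from 149.7 ± 6.48 to 64.2 ± 2.93 (-1.21). Other strongly increased genes were ATF5 (2.26), CHAC1, which degrades glutathione (2.11), SESN2 (1.99), UNC5B (1.92), DDIT3, also called CHOP (1.86), and ARMCX2 (1.85). The other most decreased were the helicase PIF1 (-2.06), PSRC1 (-1.48), HIST2H2AC (-1.45), HIST1H2BK (-1.39), CDC20 (-1.35), KLRF2 (-1.27) and CCNB1 (-1.23). All of these had limma Benjamini-Hochberg adjusted p of 0.0068 or less.

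Of 29 tested members of the list on the integrated stress and unfolded protein response, 18 rose and 9 fell in WT (19 and 9 adjusted over the list alone), with a median of 0.41; the stress sensor ERN1 rose by 1.83. The camera adjusted p was 0.00091, and 0.17 with an estimated correlation. Of 39 mitotic genes 28 fell and 5 rose (the same counts adjusted over the list alone), among them CENPF (-0.83) and BUB1 (-0.85). Their median was -0.43, and the list had a camera adjusted p = 1.8e-07, or 0.16 with an estimated correlation. Of 11 tested replication-dependent histone genes 9 fell (10 adjusted over the list alone), with a median of -1.08, including HIST1H3H (-1.92) and HIST1H1C (-1.49), and the list had a camera adjusted p = 0.00038, or 0.039 with an estimated correlation. Since library preparation is not given, how fully histone transcripts were captured, here and in KO-labelled cells, is not known. The histone median was -1.75 with limma-voom, -1.74 with a pseudocount of 0.1, -0.70 with a pseudocount of 1 and -0.66 with no filter. Genes of DNA replication went mostly the other way: 22 of 40 rose and 6 fell (23 and 6 adjusted over the list alone, median 0.18), with the licensing factor CDC6 up by 0.76 and UHRF1 down by -0.71. Its adjusted p was 0.0027, and 0.23 with an estimated correlation. Of 38 homologous recombination and fork repair genes 18 rose and 5 fell (the same adjusted over the list alone, median 0.14), with BRIP1 at 0.75 and FANCI at 0.46, and the list had a camera adjusted p = 0.0018, or 0.11 with an estimated correlation. Among cyclins and CDK inhibitors of G1, 10 of 19 rose and 3 fell (the same adjusted over the list alone, median 0.14), led by CCNE2 (1.36) and E2F8 (1.28), and the list had a camera adjusted p = 0.029, or 0.17 with an estimated correlation. With plain read totals and under TPM the mitotic median was -0.27 and -0.24, that of DNA replication 0.33 and 0.37, of fork repair 0.29 and 0.32 and of the G1 list 0.29 and 0.33. Under quantile normalization it was -0.27 for mitosis, 0.34 for DNA replication and 0.31 for the G1 list, whose call was lost with protein-coding genes only (adjusted p = 0.055).

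In the list on MYC and ribosome biogenesis 30 of 33 fell and 1 rose in WT (the same adjusted over the list alone, median -0.56), including NOP16 (-0.98) and DKC1 (-0.84), and the list had a camera adjusted p = 8.3e-12, or 0.059 with an estimated correlation. All 43 cytosolic ribosomal protein genes fell (the same adjusted over the list alone, median -0.38, adjusted p = 8.3e-12, and 0.30 with an estimated correlation), but under quantile normalization their median turned to 0.02. Of 33 B cell precursor genes 25 fell and 2 rose (the same adjusted over the list alone, median -0.41): TCF3, which encodes E2A, by -0.91, IGLL1, a surrogate light chain gene, by -1.09, and PAX5 by -0.49. Adjusted p was 9.8e-08, and 0.039 with an estimated correlation. Of 24 KMT2A-rearranged leukaemia genes 17 fell and 2 rose (the same adjusted over the list alone, median -0.25), including CSPG4 (-0.82) and FLT3 (-0.54), and the list had a camera adjusted p = 4.6e-05, or 0.039 with an estimated correlation. Cholesterol synthesis genes fell in 20 of 22 cases and rose in 2 (the same adjusted over the list alone, median -0.37), with HMGCS1 at -0.69, and the list had a camera adjusted p = 2.0e-06, or 0.079 with an estimated correlation. Of 30 glycolysis genes 17 fell and 4 rose (18 and 4 adjusted over the list alone, median -0.21, adjusted p = 0.0051, and 0.37 with an estimated correlation) and of 12 stem and progenitor genes 6 fell and 2 rose (the same adjusted over the list alone, median -0.23, adjusted p = 0.024, and 0.17 with an estimated correlation). The last 2 calls were lost under quantile normalization, and that of stem and progenitor genes also with the filter at 5 FPKM (adjusted p = 0.067), while with no filter their median was -0.02. The B cell precursor median was -0.27 under quantile normalization. With plain read totals and under TPM the medians lay nearer to 0: -0.10 and -0.06 for KMT2A-rearranged leukaemia genes, -0.07 and -0.03 for glycolysis, -0.09 and -0.05 for stem and progenitor genes, -0.26 and -0.22 for B cell precursor genes, -0.23 and -0.19 for cholesterol synthesis, -0.22 and -0.18 for ribosomal proteins and -0.41 and -0.37 for MYC and ribosome biogenesis.

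Of 18 tested NF-kB targets 11 rose and 1 fell in WT (the same adjusted over the list alone, median 0.53), with RELB at 1.47, TNFAIP3, an inhibitor of NF-kB signalling, at 1.64, and NFKB2 at 1.29, and the list had a camera adjusted p = 0.00059, or 0.11 with an estimated correlation. Of 26 interferon-stimulated genes 15 rose and 2 fell (the same adjusted over the list alone, median 0.45), with OAS3 at 1.09, and the list had a camera adjusted p = 0.00095, or 0.059 with an estimated correlation. Of 25 p53 targets 11 rose and 3 fell (the same adjusted over the list alone, median 0.10), with CDKN1A, which encodes p21, at 0.56 and BTG2 at 1.18. Of 17 glucocorticoid response genes 9 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.34), with TXNIP at 1.33. The adjusted p was 0.024 for both lists, and 0.17 for both with an estimated correlation. The p53 median was 0.25 with plain read totals and 0.29 under TPM, and the glucocorticoid median 0.50 and 0.53. Without WT untreated replicate 3 the p53 median was 0.19. With the filter at 5 FPKM the medians of the interferon-stimulated and glucocorticoid lists were 0.13 and 0.12.

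In all, 6606 of 13300 genes passed limma's Benjamini-Hochberg threshold in WT, 3200 higher and 3406 lower, and 285 of these changed at least 2-fold, 200 higher and 85 lower. The split depended on the scaling. With values rescaled to TPM the counts were 5537 higher and 1656 lower, and the median of all genes moved from -0.01 to 0.16; with plain read totals they were 5130 and 1952, with a median of 0.13. Changes given here are relative to the deposited scale. Of the 17 lists called in WT, those of B cell precursor genes, KMT2A-rearranged leukaemia genes and histones held with an estimated correlation.

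**Figure D2:**
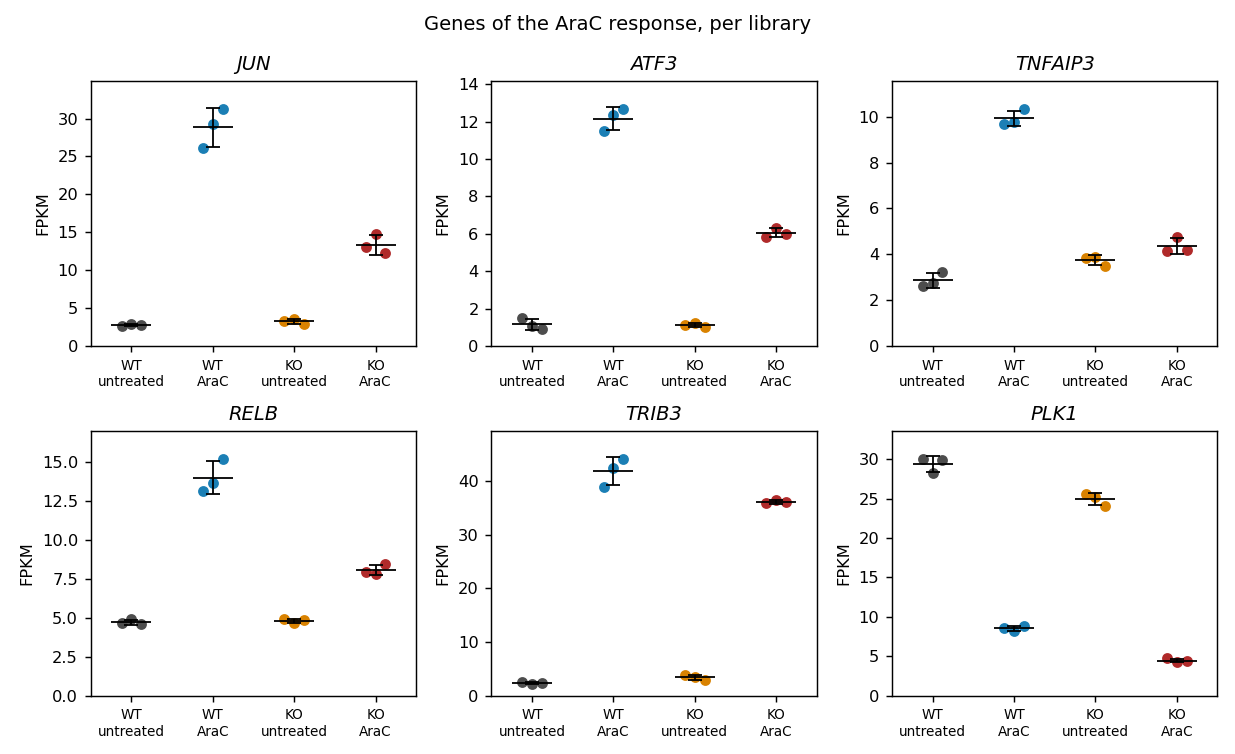
FPKM of JUN, ATF3, TNFAIP3, RELB, TRIB3 and PLK1 in each of the 12 libraries (points), with group mean and SD (bars, n = 3). JUN reached 28.9 in AraC-treated WT and 13.4 in AraC-treated KO-labelled libraries from untreated means of 2.77 and 3.28.

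The KO-labelled cells answered AraC with many of the same genes. TRIB3 went from 3.40 ± 0.48 to 36.1 ± 0.32 FPKM (SD, n = 3 each, log2 fold 3.24 ± 0.08 SE), ATF5 from 11.6 ± 0.35 to 67.9 ± 3.88 (2.50) and CHAC1 from 0.63 ± 0.04 to 5.62 ± 0.66 (2.43). The G1/S cyclins CCNE2 and CCNE1 rose by 1.99 and 1.88. PLK1 went from 25 ± 0.78 to 4.47 ± 0.24 (-2.36), PIF1 fell by 2.79, CCNB1 went from 82.3 ± 1.58 to 24.7 ± 1.98 (-1.72), and MYC from 162.8 ± 3.68 to 68.4 ± 2.94 (-1.25). Other strongly increased genes were CLGN (2.23), SPNS3 (2.15), ATF3 (2.01) and JUN (1.87), and the other most decreased HIST1H1C (-2.34), KIF20A (-1.94), HIST1H2BK (-1.83), CDC20 (-1.67), PSRC1 (-1.61), CENPE (-1.53) and AURKA (-1.47). All of these had limma Benjamini-Hochberg adjusted p of 4.7e-05 or less.

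The lists called in the KO-labelled cells had the direction they had in WT. All 11 tested histone genes fell (the same adjusted over the list alone, median -1.36, adjusted p = 1.9e-05, and 0.033 with an estimated correlation). Mitotic genes fell in 28 of 39 cases and none rose (29 fell adjusted over the list alone, median -0.48, adjusted p = 8.1e-12, and 0.070 with an estimated correlation). MYC and ribosome biogenesis genes fell in 27 of 33 cases and 1 rose (28 and 1 adjusted over the list alone, median -0.53, adjusted p = 8.1e-12, and 0.070 with an estimated correlation). Stress response genes rose in 19 of 29 cases and fell in 7 (19 and 8 adjusted over the list alone, median 0.50, adjusted p = 3.0e-05, and 0.12 with an estimated correlation). DNA replication genes rose in 25 of 40 cases and fell in 5 (27 and 5 adjusted over the list alone, median 0.19, adjusted p = 6.2e-05, and 0.14 with an estimated correlation), while MCM6 fell by 0.60. Fork repair genes rose in 20 of 38 cases and fell in 5 (21 and 6 adjusted over the list alone, median 0.17, adjusted p = 0.00044, and 0.070 with an estimated correlation), with EXO1 at 0.97. G1 cyclins and inhibitors rose in 10 of 19 cases and fell in 4 (10 and 5 adjusted over the list alone, median 0.12, adjusted p = 0.028, and 0.16 with an estimated correlation). B cell precursor genes fell in 21 of 33 cases and 2 rose (the same adjusted over the list alone, median -0.29, adjusted p = 8.6e-05, and 0.070 with an estimated correlation). KMT2A-rearranged leukaemia genes fell in 15 of 24 cases and 1 rose (17 and 1 adjusted over the list alone, median -0.24, adjusted p = 0.00014, and 0.067 with an estimated correlation). Interferon-stimulated genes rose in 15 of 26 cases and fell in 2 (15 and 3 adjusted over the list alone, median 0.40, adjusted p = 0.00060, and 0.067 with an estimated correlation).

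Ribosomal protein genes fell in 35 of 43 cases (38 adjusted over the list alone, median -0.23, adjusted p = 2.9e-07, and 0.51 with an estimated correlation), but under quantile normalization the median turned to 0.03. Cholesterol synthesis genes fell in 13 of 22 cases and rose in 2 (the same adjusted over the list alone, median -0.24, adjusted p = 0.0024, and 0.19 with an estimated correlation), a call lost under quantile normalization. Stem and progenitor genes fell in 8 of 12 cases and rose in 2 (9 and 2 adjusted over the list alone, median -0.38, adjusted p = 0.0040, and 0.10 with an estimated correlation). MHC class II genes fell in 7 of 11 cases (8 adjusted over the list alone, median -0.33, adjusted p = 0.013, and 0.070 with an estimated correlation), with CIITA, their master regulator, at -0.65. In WT 6 of the 11 fell and 2 rose, and the list did not pass (adjusted p = 0.097). In the KO-labelled cells the lists of NF-kB targets (7 of 18 rose and 5 fell, 8 and 5 adjusted over the list alone, adjusted p = 0.27), p53 targets (8 of 25 rose and 4 fell, adjusted p = 0.14), glucocorticoid response (6 of 17 rose and 3 fell, adjusted p = 0.27) and glycolysis (14 of 30 fell and 2 rose, 14 and 3 adjusted over the list alone, adjusted p = 0.072) did not pass. Of the 14 lists called there, that of histones held with an estimated correlation. With plain read totals and under TPM the KO medians were -0.11 and -0.10 for ribosomal proteins, -0.12 and -0.11 for cholesterol synthesis, -0.12 and -0.11 for KMT2A-rearranged leukaemia genes, -0.19 and -0.18 for B cell precursor genes, -0.25 and -0.24 for stem and progenitor genes, 0.31 and 0.32 for DNA replication, 0.28 and 0.29 for fork repair and 0.24 and 0.25 for the G1 list. Under quantile normalization they were -0.17 for B cell precursor genes, -0.12 for KMT2A-rearranged leukaemia genes, -0.19 for stem and progenitor genes, 0.30 for DNA replication and 0.23 for the G1 list. With no filter they were -0.61 for histones and -0.04 for stem and progenitor genes. Fitted to the KO-labelled libraries alone, the G1 list lost its call (adjusted p = 0.053).

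Other lists were not shifted by AraC in either genotype. Among 13 BCL2 family genes, BID fell by 0.50 in WT and by 0.49 in KO-labelled cells, and BAD rose by 0.68 and 0.61. Among 25 dNTP synthesis genes, RRM2, a subunit of ribonucleotide reductase, rose by 0.86 and 1.14, and TYMS by 0.45 and 0.61. Among 24 JAK-STAT and cytokine receptor genes, CSF2RB rose by 1.08 and 0.93 and PTPN6 fell by 0.48 and 0.61. Among 33 adhesion and cytoskeleton genes, ITGA4 fell by 0.78 and 0.71. Among 18 AP-1 and immediate early genes, 5 rose and 7 fell in WT and 3 rose and 6 fell in KO-labelled cells. Of 9 tested myeloid markers CEBPB rose by 1.08 and 1.22, and of 7 tested T and NK cell markers NOTCH1 fell by 0.30 and 0.43. Of 13 mitochondrially encoded genes 1 fell in WT, MT-CO2 by 0.22, and 0 passed adjusted over the list alone or in KO-labelled cells. Only 3 erythroid and megakaryocyte markers were tested, too few for the set test; TFRC, the transferrin receptor, fell by 0.86 and 0.64.

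In the KO-labelled libraries 5907 genes passed limma's Benjamini-Hochberg threshold, 2628 higher and 3279 lower, and 236 changed at least 2-fold, 166 higher and 70 lower. Rescaled to TPM the split was 4056 higher and 1755 lower, and with plain read totals 3991 and 1901. The AraC calls of both genotypes shared 2036 higher genes, where 632.3 would be shared by independent lists of those sizes, and 2485 lower genes, where 839.7 would be. Only 53 genes were called in opposite directions. Both comparisons use the same variance estimate per gene, so the figures for independent lists are a reference and no chance level. Across the 13300 genes, which are not independent replicates, the 2 AraC effects correlated at Pearson's r = 0.695 and Spearman's rho = 0.729.

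Over the 7834 genes called for the average AraC effect, the slope of the KO effect on the WT effect was 0.912. The response score, the mean log2 change of these genes in their average direction, was 0.395 ± 0.0037 in the treated WT libraries and 0.355 ± 0.011 in the treated KO-labelled libraries (SD, n = 3 each). All 3 KO-labelled scores lay under all 3 WT scores, which gives a two-sided exact permutation p = 0.10, the smallest this design allows. Each score was taken against the mean of the 3 untreated libraries of its genotype. An error in that mean would move all 3 scores of the genotype together. The SD and the permutation p leave out this spread of the untreated libraries, so they do not settle whether the response sizes differ. Of these genes, 58.4% had the smaller absolute effect in the KO-labelled libraries. The slope depended on the gene choice: over genes called in WT alone it was 0.828 and over genes called in KO alone 1.03.

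**Figure D3:**
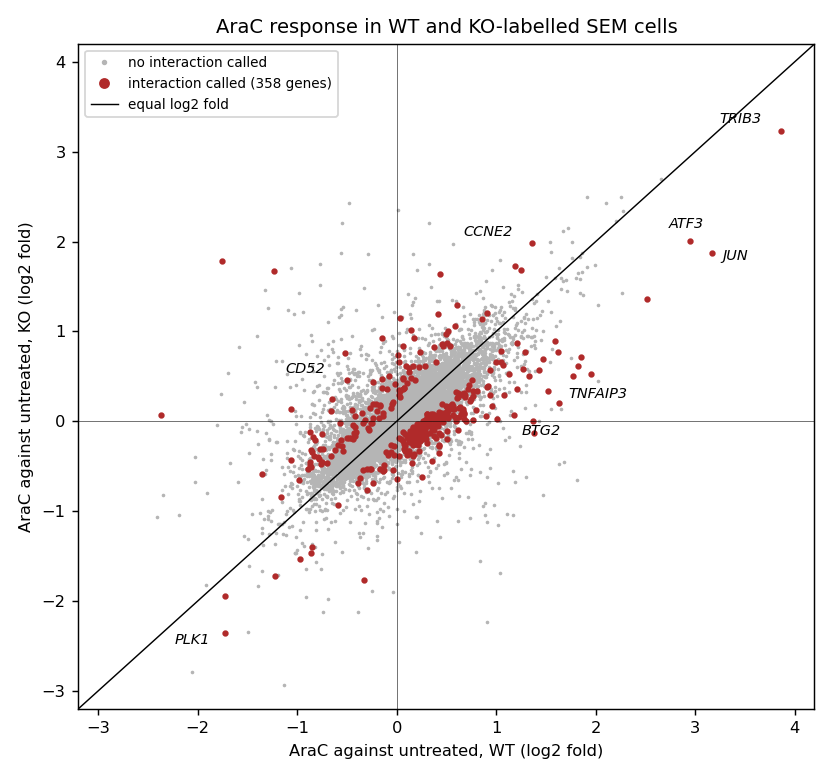
Log2 fold of AraC against untreated in WT (horizontal) and KO-labelled (vertical) cells on the log2(FPKM + 0.5) scale, 1 point per tested gene, with the 358 genes past the interaction test in red and the line of equal folds. JUN lay at 3.17 and 1.87, TNFAIP3 at 1.64 and 0.20, and PLK1 at -1.72 and -2.36.

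Without AraC, the KO-labelled libraries differed from WT in genes such as MS4A1 and CD9, in several genes that were almost silent, and along chromosomes 13 and 8. MS4A1, which encodes the B cell antigen CD20 (chromosome 11, 60455752 to 60470760), was at 6.76 ± 0.20 FPKM in KO-labelled and 0.26 ± 0.09 in WT libraries (SD, n = 3 each, log2 difference 3.26 ± 0.09 SE). PER3, a circadian clock gene, was at 12.3 ± 0.44 against 1.64 ± 0.30 (2.59), ALDH1A1, a retinaldehyde dehydrogenase, at 5.55 ± 0.75 against 0.72 ± 0.21 (2.31) and CAMK2D at 41.2 ± 2.99 against 8.49 ± 0.19 (2.21). The other most increased genes were OAT (2.09), TRIM72 (2.01), TOX (1.83), HOPX (1.71), FCRLA (1.68) and CD70 (1.51). CD9, a tetraspanin of the B cell precursor surface, was at 1.44 ± 0.13 against 7.44 ± 0.77 (-2.04), and MCOLN2 (-2.69), BEX3 (-2.39), CIDEB (-1.81), PKN3 (-1.74) and LSP1 (-1.61) were lower too. All had limma Benjamini-Hochberg adjusted p of 2.6e-05 or less.

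Of the genes named by the rule, KLRF2, C4orf48, NPW and RTL8C were reduced most in the untreated KO-labelled libraries. KLRF2, a lectin-like receptor gene (chromosome 12, 9881489 to 9895833), had 10 reads over the 3 untreated KO-labelled libraries and 3994 over the 3 WT ones, at 116.3 ± 6.42 FPKM in WT. Its WT level was 399.5 times as high, with a 95% counting interval of 217.0 to 833.7. NPW, which encodes neuropeptide W, had 5 reads against 764, a ratio of 152.8 (65.2 to 472.0). C4orf48 had 0 reads in all 6 KO-labelled libraries and 13.1 ± 2.71 FPKM in untreated WT, so it was at least 37.0-fold lower against a floor of 3 reads per library. RTL8C had 0 reads in the untreated KO-labelled libraries and was at least 43.9-fold lower. The fitted log2 differences of these 4 genes (-7.23, -4.61, -4.75 and -3.92) depend on the pseudocount and are no bounds; their adjusted p were 1.2e-08 or less.

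In the list of B cell precursor genes, 16 of 33 were higher and 6 lower in the untreated KO-labelled libraries. Adjusted over the list alone the counts were 17 and 6, and the median of the list was 0.17. CD22 was at 0.81, IL7R, the interleukin 7 receptor, at 0.61 and LEF1 at 0.57, while CD9, given above, is among the lower members. The list had a camera adjusted p = 0.0068, or 0.28 with an estimated correlation. MHC class II genes were higher in 7 of 11 cases and lower in 0 (the same adjusted over the list alone, median 0.33), including HLA-DRA (0.49) and HLA-DMA (0.53), and the list had a camera adjusted p = 0.0015, or 0.12 with an estimated correlation. Adhesion and cytoskeleton genes were higher in 19 of 33 cases and lower in 4 (the same adjusted over the list alone, median 0.20), with the integrin ITGB7 at 1.09 and ANXA2 at -0.63, and the list had a camera adjusted p = 0.0015, or 0.44 with an estimated correlation. Of 17 glucocorticoid response genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone, median 0.19), with the kinase SGK1 at 1.10, and the list had a camera adjusted p = 0.025, or 0.28 with an estimated correlation. This call was lost without KO untreated replicate 1 (adjusted p = 0.053), with protein-coding genes only (0.055) and with the filter at 5 FPKM (0.069). Of 9 tested myeloid markers 8 were lower (the same adjusted over the list alone, where 1 was also higher, median -0.63), among them CEBPA (-0.56), CSF1R (-0.63) and AIF1 (-1.02), and the list had a camera adjusted p = 0.00051, or 0.28 with an estimated correlation. With the filter at 5 FPKM the myeloid call was lost (median -0.29, adjusted p = 0.12), and with no filter its median was -0.19 and that of adhesion genes 0.12. No list call between the genotypes held with an estimated correlation. Single members of lists that did not pass included the runt factor RUNX2 (1.04) and LMO2 (-0.92).

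Of 20 tested genes of cytarabine transport and metabolism, 4 were higher and 3 lower without AraC (the same adjusted over the list alone), and the list did not pass (adjusted p = 0.74). SAMHD1, a dNTP triphosphohydrolase that also hydrolyses the active triphosphate of AraC, was at 24.1 ± 0.76 FPKM in KO-labelled and 10.8 ± 0.60 in WT libraries (chromosome 20, 36889773 to 36951901, log2 difference 1.13 ± 0.05 SE, limma adjusted p = 8.9e-08). SLC29A1, the equilibrative nucleoside transporter that imports AraC, was at 18.8 ± 0.86 against 25.3 ± 0.30 (-0.42). SLC29A2 was at 2.10 ± 0.11 against 1.09 ± 0.32 (0.73), and the exporter ABCC4, on chromosome 13, was lower by -0.57. DCK, the kinase that activates AraC, was at 55.2 ± 5.40 against 52.1 ± 3.01 and did not pass (0.08, adjusted p = 0.46). NME2 (-0.51), DCTD (0.19) and NT5C2 (0.16) passed at limma adjusted p = 0.034, 0.027 and 0.019. All 3 calls were lost without WT untreated replicate 2, KO untreated replicate 2 or KO untreated replicate 3 (adjusted p from 0.053 to 0.13), and those of NME2 and DCTD also without WT untreated replicate 3 (0.067 and 0.093). CMPK1, DGUOK, TK2, SLC29A3, NME1, DCTPP1, NT5C, NT5C3A, NT5E, ABCC5, ABCC10 and ABCB1 did not pass without AraC, with log2 differences from -0.07 to 0.21.

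With AraC, SAMHD1 remained higher in the KO-labelled libraries (19.96 ± 1.24 against 10.7 ± 0.30 FPKM, 0.87, limma adjusted p = 7.9e-07) and ABCC4 lower (-0.46). SLC29A1 was at 17.1 ± 0.31 against 18.8 ± 0.83 (-0.13, adjusted p = 0.039), a call that held without WT AraC replicate 2 or any of the KO untreated replicates and was lost without any 1 of the other 8 libraries (adjusted p from 0.052 to 0.14). DCK was at 57.7 ± 3.22 against 50.3 ± 1.98 and did not pass (0.20, adjusted p = 0.058). AraC itself lowered NME1 by -0.66 in WT and -0.75 in KO-labelled cells and the pyrophosphatase DCTPP1 by -0.47 and -0.45. It lowered SLC29A1 by -0.42 and -0.13, and ABCC4 by -0.43 and -0.32, and raised ABCB1 by 0.99 in WT, with 0.38 in KO-labelled cells (adjusted p = 0.070). The list as a whole was not shifted by AraC in WT (3 rose and 5 fell, 2 and 4 adjusted over the list alone, adjusted p = 0.34) or in KO-labelled cells (2 rose and 9 fell, adjusted p = 0.30). The SLC29A1 effect in KO-labelled cells did not pass without KO untreated replicates 1 or 3 (adjusted p = 0.081 and 0.095) or KO AraC replicates 1 or 3 (0.082 and 0.055), and under TPM that effect was 0.00021.

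Genes of chromosome 13 had a median log2 difference of -0.49 and genes of chromosome 8 of -0.28 in untreated KO-labelled against WT libraries; with AraC the medians were -0.43 and -0.25. The other chromosomes had medians from -7.7e-05 to 0.055 without AraC. Without AraC, 147 of 225 tested genes of chromosome 13 and 250 of 461 of chromosome 8 were lower, together 23.6% of all lower calls from 5.16% of tested genes. This applies to RB1 (-0.53), ABCC4, SPRY2 (-0.60), RFC3 (-0.60) and IRS2 (-0.60) on chromosome 13 and to TNFRSF10B (-0.93), CCNE2 (-0.69), MCM4 (-0.40), WRN (-0.36), RPL7 (-0.38) and RPL8 (-0.32) on chromosome 8, while TOX, also on chromosome 8, was higher. Chromosomes were looked at after the data were seen.

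**Figure D4:**
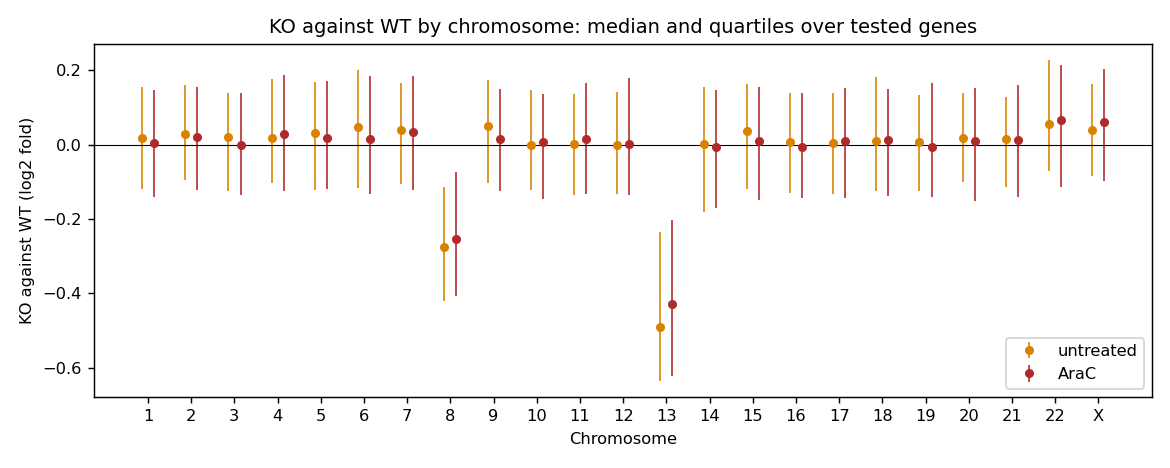
Median (points) and quartiles (lines) of the KO-labelled against WT log2 difference over the tested genes of each chromosome, without and with AraC. Chromosome 13 lay at -0.49 and -0.43 and chromosome 8 at -0.28 and -0.25; all other medians lay between -0.0074 and 0.066.

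In all, 3657 genes differed between the untreated genotypes by limma's Benjamini-Hochberg test, 1976 higher and 1681 lower in the KO-labelled libraries, and 289 by at least 2-fold (128 higher, 161 lower). Which direction was the more frequent depended on the scaling: rescaled to TPM 1787 were higher and 1859 lower, and with plain read totals 1798 and 1958. Without chromosomes 13 and 8 the count was 3235, with 1951 higher and 1284 lower. The lists on JAK-STAT receptors (11 of 24 higher, 4 lower), interferon-stimulated genes (11 of 26 higher, 2 lower, 12 and 2 adjusted over the list alone), mitosis (11 of 39 higher, 4 lower, 12 and 5 adjusted over the list alone), KMT2A-rearranged leukaemia genes (9 of 24 higher, 5 lower) and p53 targets (7 of 25 higher, 3 lower) did not pass, with adjusted p from 0.060 to 0.22.

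With AraC, MS4A1 (7.07 ± 0.25 against 0.57 ± 0.09 FPKM, SD, n = 3 each, log2 difference 2.82 ± 0.09 SE), PER3 (2.23), ALDH1A1 (2.03) and CAMK2D (1.87) again led the genes higher in the KO-labelled libraries, with RIPOR2 (1.64), OAT (1.61), UGT3A2 (1.60), TRIM72 (1.59), RIBC2 (1.53) and HTR1F (1.52). Lower genes included KLRF2, with 4 reads against 2100, NPW, with 7 against 736, and IQCC, with 41 against 991, a ratio of 20.7 (15.2 to 29.1). RTL8C had 1 read against 644, a ratio of 552.2 with a counting interval of 98.8 to 21842.6. MAPK11 (-2.55), BEX3 (-2.24), CIDEB (-1.63), CD9 (-1.58) and IRAK2 (-1.53), a kinase of Toll-like receptor signalling, were lower too. These folds had limma Benjamini-Hochberg adjusted p of 4.9e-05 or less.

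Of 33 B cell precursor genes 21 were higher and 4 lower with AraC (23 and 5 adjusted over the list alone, median 0.24). Higher members included IGLL1 (1.03), VPREB3 (1.38) and IL7R (0.81), and CD9, given above, was again among the lower ones. The list had a camera adjusted p = 6.4e-06, or 0.17 with an estimated correlation. NF-kB targets were lower in 11 of 18 cases and higher in 2 (the same adjusted over the list alone, median -0.34), with TNFAIP3 at -1.10, TNFAIP2 at -1.03 and RELB at -0.76, and the list had a camera adjusted p = 0.0064, or 0.32 with an estimated correlation. Cholesterol synthesis genes were higher in 13 of 22 cases and lower in 1 (13 and 2 adjusted over the list alone, median 0.17), with INSIG1 at 0.74, and the list had a camera adjusted p = 0.0027, or 0.32 with an estimated correlation. Myeloid markers were lower in 6 of 9 cases (8 adjusted over the list alone, where 1 was higher, median -0.57, adjusted p = 0.0017, and 0.32 with an estimated correlation). Adhesion genes were higher in 15 of 33 cases and lower in 5 (17 and 6 adjusted over the list alone, median 0.18, adjusted p = 0.0032, and 0.49 with an estimated correlation). MHC class II genes were higher in 5 of 11 cases (8 adjusted over the list alone, where 1 was lower, median 0.32, adjusted p = 0.012, and 0.20 with an estimated correlation). Ribosomal protein genes were higher in 26 of 43 cases (32 adjusted over the list alone, where 2 were lower, median 0.18, adjusted p = 2.3e-06, and 0.78 with an estimated correlation), a call that quantile normalization ended at a median of 0.0062. Under TPM the median was 0.09 for cholesterol synthesis, 0.11 for adhesion and 0.10 for ribosomal proteins, and under quantile normalization it was 0.08 for adhesion. Without KO AraC replicate 3 the ribosomal protein median was 0.12. With no filter the medians were 0.09 for adhesion and -0.20 for myeloid markers, and with the filter at 5 FPKM the myeloid and MHC class II calls were lost (medians -0.18 and 0.20, adjusted p = 0.32 and 0.094).

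This comparison called 4018 genes by limma's Benjamini-Hochberg test, 2047 higher and 1971 lower, and 238 of at least 2-fold (110 higher, 128 lower). Rescaled to TPM the split was 1353 higher and 3036 lower, and with plain read totals 1567 and 2761. The KO-labelled against WT calls without and with AraC shared 1197 higher genes (304.1 if independent) and 1053 lower genes (249.1 if independent), with 47 in opposite directions. As for the AraC calls, the figures for independent lists are no chance level. Without chromosomes 13 and 8 the count with AraC was 3629, with 2021 higher and 1608 lower.

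The interaction asks which genes answered AraC differently in the KO-labelled cells. Among 18 tested NF-kB targets 6 passed with a negative interaction, which is a lower AraC effect in the KO-labelled cells. Passing or not, 16 of the 18 were negative. Among 18 AP-1 and immediate early genes 3 passed with a negative interaction. Neither list passed with an estimated correlation (camera adjusted p = 0.15 and 0.49). TNFAIP3 (chromosome 6, 137867188 to 137883312) went from 2.87 ± 0.33 to 9.94 ± 0.33 FPKM in WT and from 3.75 ± 0.21 to 4.38 ± 0.34 in KO-labelled cells (SD, n = 3 each, interaction -1.44 ± 0.11 log2 SE, limma Benjamini-Hochberg adjusted p = 0.00029). JUN reached 28.9 ± 2.57 in WT and 13.4 ± 1.31 in KO-labelled cells (-1.29, adjusted p = 0.0011), ATF3 12.2 ± 0.60 and 6.06 ± 0.25 (-0.94, adjusted p = 0.015) and RELB 14 ± 1.06 and 8.07 ± 0.35 (-0.78, adjusted p = 0.0014). BTG2, an antiproliferative p53 target, rose from 7.83 ± 0.18 to 18.4 ± 1.99 in WT, and stood at 18.3 ± 0.44 before and 19.1 ± 0.47 after AraC in KO-labelled cells (-1.11). TXNIP, an inhibitor of glucose uptake, rose by 1.33 in WT and 0.51 in KO-labelled cells (-0.82).

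Of 39 mitotic genes 6 passed with a negative interaction, among them PLK1 (-0.64), AURKA (-0.60), CENPE (-0.56) and CCNB1 (-0.49). AraC lowered these named genes in both genotypes, so here a negative interaction means a larger fall in KO-labelled cells. The median AraC effect of the mitotic list was -0.43 in WT and -0.48 in KO-labelled cells. This list did not pass with an estimated correlation either (camera adjusted p = 0.40). CCNE2 rose further there (0.62), from a lower untreated level of 7.84 ± 0.48 against 12.9 ± 0.33 FPKM. CD52, a lymphocyte surface antigen, went from 19.3 ± 1.55 to 13.5 ± 1.36 in WT and from 6.97 ± 1.16 to 9.67 ± 0.33 in KO-labelled cells (0.95, adjusted p = 0.012). PKN3 (0.77), RAB15 (0.69), DOK3 (0.67) and PRPS2 (0.63) also had a positive interaction, and IGLL5 (-0.87), DNAJB2 (-0.85) and the chemokine gene CCL5 (-0.85) a negative one. The interaction calls of the genes from TNFAIP3 to CCL5 held with any 1 library left out.

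By list, the interaction was negative for NF-kB targets (6 of 18 passed, all negative, 8 negative and 1 positive adjusted over the list alone, median -0.30, adjusted p = 5.8e-07, and 0.15 with an estimated correlation) and mitotic genes (6 of 39 passed, all negative, 19 negative and 1 positive adjusted over the list alone, median -0.16, adjusted p = 5.8e-07, and 0.40 with an estimated correlation). For mitotic genes, which AraC mostly lowered, a negative value means a larger fall in KO-labelled cells. The interaction was negative too for AP-1 and immediate early genes (JUN, ATF3 and DUSP1 passed of 18, also adjusted over the list alone, median -0.11, adjusted p = 0.020, and 0.49 with an estimated correlation). The glucocorticoid response list had a median of -0.07 (4 of 17 passed as negative and 1 as positive, 7 and 1 adjusted over the list alone, adjusted p = 0.045, and 0.40 with an estimated correlation). Its call was lost with plain read totals, TPM, quantile normalization, sample weights, the replicate block, protein-coding genes only and the filter at 5 FPKM (adjusted p from 0.050 to 0.10). The median of this list was -0.17 with limma-voom, -0.13 with sample weights and -0.12 with a pseudocount of 0.1. It was positive for cholesterol synthesis genes (INSIG1 and LSS passed of 22, 8 adjusted over the list alone, median 0.17, adjusted p = 5.8e-07, and 0.18 with an estimated correlation) and B cell precursor genes (0 of 33 passed, 10 positive and 2 negative adjusted over the list alone, median 0.11, adjusted p = 0.0012, and 0.24 with an estimated correlation). It was also positive for ribosomal protein genes (0 of 43 passed, median 0.14, adjusted p = 5.8e-07, and 0.56 with an estimated correlation), dNTP synthesis genes (RRM2 passed of 25, 3 adjusted over the list alone, median 0.08, adjusted p = 0.0064, and 0.49 with an estimated correlation), mitochondrially encoded genes (0 of 13 passed, median 0.16, adjusted p = 0.011, and 0.56 with an estimated correlation) and glycolysis genes (median 0.11, adjusted p = 0.045, and 0.60 with an estimated correlation). Of the 30 glycolysis genes only TXNIP passed, in the negative direction. Quantile normalization ended the calls of the ribosomal protein, dNTP synthesis, mitochondrially encoded and glycolysis lists, and the filter at 5 FPKM that of glycolysis (adjusted p = 0.064). With plain read totals the dNTP median was 0.04. Under TPM the median was 0.06 for B cell precursor genes, 0.12 for cholesterol synthesis, 0.08 for ribosomal proteins, 0.02 for dNTP synthesis, 0.10 for mitochondrially encoded genes, 0.05 for glycolysis, -0.17 for the AP-1 list and -0.13 for the glucocorticoid list. On leaving out a library, the AP-1 list lost its call without KO untreated replicate 2, KO AraC replicate 1 or KO AraC replicate 3 (adjusted p = 0.066, 0.059 and 0.055, medians -0.07, -0.09 and -0.08), the mitochondrially encoded list without WT untreated replicate 2, WT AraC replicate 3 or KO AraC replicate 3 (0.056, 0.066 and 0.052, medians 0.15, 0.14 and 0.08) and dNTP synthesis without KO AraC replicate 3 (0.068, median 0.04). The glucocorticoid list lost it without WT untreated replicate 2 (0.11), WT AraC replicate 3 (0.080), KO untreated replicate 1 (0.084) or 2 (0.055), or KO AraC replicate 1 (0.059), 2 (0.067) or 3 (0.068). Its median all but vanished without WT untreated replicate 2 (-0.00060) and was -0.15 without WT untreated replicate 1 or KO AraC replicate 3, and -0.11 without WT untreated replicate 3 or WT AraC replicate 2. Glycolysis lost it without WT untreated replicate 1 (0.10) or 3 (0.17), WT AraC replicate 1 (0.091) or 2 (0.090), KO untreated replicate 2 (0.066) or 3 (0.17, median 0.07), or KO AraC replicate 1 (0.059) or 3 (0.068). Without KO AraC replicate 3 the medians of B cell precursor genes and ribosomal proteins were 0.07 and 0.08. The call of LSS was lost without any 1 of 10 libraries, all but KO untreated replicate 1 and KO AraC replicate 3 (adjusted p from 0.054 to 0.11), and that of RRM2 without any 1 of 8, all but WT untreated replicate 2, KO untreated replicate 1 and KO AraC replicates 2 and 3 (0.050 to 0.075). The stress response list was not shifted (median 0.03, adjusted p = 0.99), although 5 of 29 passed, 1 positive and 4 negative (3 and 6 adjusted over the list alone), TRIB3 (-0.63) and the amino acid transporter subunit SLC3A2 (-0.37) among them. Nor were p53 targets (median -0.08, adjusted p = 0.091) or genes of cytarabine transport and metabolism (median -0.07, adjusted p = 0.82), where SAMHD1 had -0.25 (adjusted p = 0.10).

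In all, 358 genes passed limma's Benjamini-Hochberg test for the interaction, 118 positive and 240 negative, 20 of them by at least 2-fold. Rescaled to TPM it was 94 positive and 493 negative. The count fell by more than 1.5 times without WT untreated replicates 1, 2 or 3 (164, 187 and 142), WT AraC replicates 1, 2 or 3 (205, 127 and 155), KO untreated replicates 2 or 3 (150 and 175) and KO AraC replicate 1 (168).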

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

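The 3 tests on the NF-kB list in this part were chosen only after the result was seen, in place of earlier ones that could not have come out otherwise (on 9 genes selected by their interaction, and on a scaling that moves every gene of a library alike).

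The AraC effect differed between the genotype labels for 358 genes by limma's interaction test with Benjamini-Hochberg adjustment. For 100 regroupings, genotype was relabelled within each treatment after the additive effects of genotype and treatment had been removed. The highest other count was 4, and 1 of the 100, the real one, reached 358. This argues against a chance division of these libraries, provided that they are independent replicates, which the labels do not say. If the libraries of a group came from 1 culture, differences between cultures would fall on the real grouping alone, and they are not excluded. For AraC in WT (6606 genes, highest other split 1), AraC in KO (5907, highest other 1), KO against WT untreated (3657, highest other 0) and with AraC (4018, highest other 1), 1 of 10 splits reached the real count, which is too few splits for a share under 0.05.

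TNFAIP3 (-1.44), RELB (-0.78) and 4 other members of the NF-kB list passed the interaction threshold, all negative. JUN (-1.29), ATF3 (-0.94) and DUSP1 of the AP-1 list (median -0.11) passed as negative too. Over all 18 tested NF-kB members, 16 of them negative, the median was -0.30 (camera adjusted p = 0.15 with an estimated correlation). An AraC effect that is weaker overall in KO-labelled cells would leave the NF-kB list at about 0 once the WT effect times the overall slope is taken off. With the lowest slope found for any choice of genes, 0.828, the median left was -0.23, and -0.21 or lower with any 1 library left out, which argues against that explanation as the whole cause. The list median itself was -0.22 or lower with any 1 library left out, and under quantile normalization, which does not move every gene of a library alike, it was -0.29, and -0.20 or lower with any 1 library left out, which argues against 1 library or the authors' scaling as the cause. A candidate explanation, as a hypothesis found and examined on the same libraries, is that KO-labelled cells induce NF-kB targets less under AraC, and whether IKZF1 loss or another difference between the lines would account for it was not tested.

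Other genes had a negative interaction: the antiproliferative gene BTG2 -1.11, the immunoglobulin lambda-like gene IGLL5 -0.87, the co-chaperone gene DNAJB2 -0.85, the chemokine gene CCL5 -0.85 and TXNIP, an inhibitor of glucose uptake, -0.82. SNAI1, which encodes the transcription factor Snail, had -0.79, a call lost without any 1 library except WT untreated replicate 3 and KO AraC replicate 2 (limma adjusted p from 0.053 to 0.085). IQCC had -0.84, which did not pass without WT untreated replicate 1, WT AraC replicate 1 or WT AraC replicate 3 (adjusted p = 0.054, 0.056 and 0.062), and was -0.50 with a pseudocount of 0.1 (adjusted p = 0.33) and -0.20 with limma-voom (0.87), so the interaction of this gene, with 57 reads over the 6 KO-labelled libraries, depends on the pseudocount.

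A positive interaction was found for CD52 0.95, PKN3 0.77, RAB15 0.69, DOK3 0.67, PRPS2, a phosphoribosyl pyrophosphate synthetase, 0.63 and the cyclin CCNE2 0.62. HYI had 0.88, lost without any 1 of 9 libraries (all but WT untreated replicate 2, KO untreated replicate 1 and KO AraC replicate 3, limma adjusted p from 0.051 to 0.072). PCLAF, a PCNA partner, had 0.77, lost without any of the WT untreated replicates, WT AraC replicates 2 or 3 or KO untreated replicate 2 (0.054 to 0.066). FAM69B had 0.75, lost without WT untreated replicates 2 or 3, WT AraC replicate 3, KO untreated replicate 2 or KO AraC replicate 1 (0.052 to 0.058). MOSPD3 had 0.68, lost without WT untreated replicates 1 or 2, WT AraC replicates 1 or 2, KO untreated replicates 2 or 3 or KO AraC replicate 2 (0.058 to 0.072). SLC29A1, the importer of AraC, had 0.29, lost without any 1 of 8 libraries (all but WT AraC replicate 1, KO untreated replicates 1 and 3 and KO AraC replicate 3, 0.057 to 0.072), and it had 0.23 under TPM (adjusted p = 0.088).

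By camera with a preset correlation, 8 further lists had a shifted interaction, none of them with an estimated correlation. The medians were 0.17 for cholesterol synthesis, 0.16 for mitochondrially encoded genes, 0.14 for cytosolic ribosomal proteins, 0.11 for B cell precursor genes, 0.11 for glycolysis and glucose uptake, 0.077 for dNTP synthesis, -0.069 for the glucocorticoid response and -0.16 for G2/M and mitosis. For G2/M and mitosis, whose genes AraC mostly lowered, the negative value means a larger fall in KO-labelled cells. Several of the 8 lists moved with a single library. Without KO AraC replicate 3 the medians were 0.037 for dNTP synthesis and 0.082 for mitochondrially encoded genes (calls lost, adjusted p = 0.068 and 0.052), 0.079 for ribosomal proteins, 0.066 for B cell precursor genes and -0.15 for the glucocorticoid response. The glucocorticoid median was -0.00060 without WT untreated replicate 2 (call lost, 0.11), and that of glycolysis 0.068 without KO untreated replicate 3 (call lost, 0.17). The report names the other libraries without which these calls were lost.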

How the results depend on the processing

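Of the alternatives, scaling by plain read totals was chosen after seeing the data. The counts of genes changed by AraC in WT and in KO stayed within 1.5 times under every alternative run. So did the counts differing between KO and WT, without and with AraC. The genes behind these counts changed more. Under TPM 4856 of the 6606 calls for AraC in WT stayed called in their direction, and 6222 kept their direction. For AraC in KO these were 4383 and 5822 of 5907. For KO against WT, 3372 of 3657 calls without AraC and 3322 of 4018 with AraC stayed. Quantile normalization kept 5404, 4660, 3411 and 3726 of these calls, in the same order. The interaction count (358) was 557 with protein-coding genes only, 587 under TPM, 652 with sample weights, 625 with limma-voom on the recovered reads and 548 with plain read totals, and 127 (without WT AraC replicate 2) to 341 (without KO AraC replicate 3) on leaving out a library. The cause was not tested. The fit with only the groups compared gives no interaction value, since the interaction uses all 4 groups. The replicate numbers were not taken to pair libraries: the deviations of 18 same-numbered pairs correlated at -0.05 to 0.12, 1 of them over 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate block the interaction count was 238, of which 230 were among the 358, and the other counts stayed within 1.5 times.

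IKZF1 in untreated KO-labelled against WT libraries kept its direction throughout and passed at -0.10 under TPM, quantile normalization and plain read totals (limma adjusted p = 0.037, 0.037 and 0.026, against 0.12 on the deposited scale, with 0.061 to 0.16 under the other planned settings that keep all libraries). The slope of the KO on the WT response (0.912) was 0.929 with a pseudocount of 0.1, 0.864 under TPM, 0.884 under quantile normalization, 0.931 with sample weights, 0.939 with limma-voom, 0.886 with plain read totals, 0.828 over genes called in WT alone and 1.03 over genes called in KO alone, with 0.889 to 0.944 on leaving out a library. Choosing genes by their call in 1 genotype favours that genotype by construction, and for the other settings the cause was not tested.

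The number of lists shifted (17 and 14 for AraC in WT and KO, 5 and 7 for KO against WT without and with AraC, 10 for the interaction) was 11 for the untreated KO against WT comparison with no filter, and 5 for the interaction under quantile normalization and 5 to 10 on leaving out a library (5 without KO AraC replicate 3). With an estimated correlation the 5 numbers were 3, 1, 0, 0 and 0. By fry, which does not compare a list with other genes, 23 lists moved one way with AraC in KO, 14 and 15 differed between KO and WT without and with AraC, and 27, 27, 26, 27 and 23 changed in either direction.

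For the genes named by the fixed rule, 407 results had 10845 values under alternatives. In settings that keep all libraries 5775 were counted as staying on their side of the threshold, 90 fell short of it and 92 passed it. On leaving out a library these counts were 4720, 155 and 9. For results that did not pass on the deposited scale, a turn of direction was not counted separately. Such turns are among those counted as staying, whether or not they then passed. Among results that passed on the deposited scale, 4 values turned their direction. SLC29A1 with AraC in KO was 0.00021 under TPM. Under quantile normalization RPS7 was 0.013 in WT and 0.010 in KO, and RPL10 was 0.048 in KO. The cause was not tested. Depth limits the low genes: 3 reads of C4orf48 correspond to 0.355 FPKM, so lower levels of it were not detectable.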

Other observations

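The 34 gene sets and the 23 chromosomes described in this part were chosen only after the data were seen, and the condition that the value for other biotypes must hold with every library left out was added after that value was seen. Of the sets, 24 are transcription factor families from the annotation column of the deposited table, and p-values were adjusted over all 34 within a comparison.

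AraC raised all 5 genes of serine and one-carbon synthesis in both genotypes. In WT and KO-labelled cells PSAT1 rose by 0.51 and 0.51, PSPH by 0.51 and 0.50, MTHFD2 by 0.47 and 0.46, SHMT2 by 0.41 and 0.51 and PHGDH, which makes the committed step of serine synthesis, by 0.30 and 0.30, with limma Benjamini-Hochberg adjusted p of 0.00035 or less. The set had medians of 0.47 and 0.50 (camera adjusted p = 0.0090 and 0.0061, and 0.33 and 0.56 with an estimated correlation). Ligands of the natural killer receptor NKG2D rose as well: ULBP1 by 1.71 and 1.45, ULBP2 by 1.80 and 1.59, ULBP3 by 0.53 and 0.46 and MICB by 0.23 and 0.28, while MICA had 0.23 in WT (adjusted p = 0.15) and rose by 0.40 in KO-labelled cells. This set passed in KO-labelled cells (median 0.46, adjusted p = 0.026, and 0.56 with an estimated correlation) and not in WT (median 0.53, adjusted p = 0.054). Neither set had a shifted interaction (adjusted p = 0.94 and 0.94). Of 37 aminoacyl-tRNA synthetase genes 21 fell in each genotype, with 7 rising in WT and 3 in KO-labelled cells. Their median was -0.17 in WT (adjusted p = 0.097), which turned to 0.02 under TPM, and -0.19 in KO-labelled cells (adjusted p = 0.030, and 0.63 with an estimated correlation), where it was -0.07 with plain read totals, -0.06 under TPM and -0.12 under quantile normalization, and the call was lost without KO untreated replicate 2 (0.056) or KO AraC replicate 1 (0.072) or 2 (0.054). Of 22 host genes of small nucleolar RNAs 13 fell and 0 rose in KO-labelled cells (median -0.31, adjusted p = 0.0061, and 0.60 with an estimated correlation, and a median of -0.20 with plain read totals and -0.19 under TPM), and 7 fell and 4 rose in WT (adjusted p = 0.36).

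The C2H2 zinc finger genes were the largest of these sets, with 449 tested members. As a set they had a lower AraC effect in KO-labelled than in WT cells. In WT 159 rose and 49 fell (median 0.14, camera adjusted p = 0.0018, and 0.096 with an estimated correlation), and the median was 0.27 with plain read totals, 0.30 under TPM and 0.09 under quantile normalization. In KO-labelled cells 69 rose and 74 fell, with a median of -0.01 that turned to 0.10 with plain read totals and 0.11 under TPM (adjusted p = 0.83). The interaction median was -0.11 (adjusted p = 2.7e-07, and 0.0095 with an estimated correlation), and it was -0.14 with plain read totals, -0.17 under TPM and -0.11 under quantile normalization. Of the single genes 28 passed as negative and 0 as positive, and 421 did not pass. Under TPM the median of all tested genes was 0.16 for AraC in WT, 0.09 in KO and -0.06 for the interaction. With AraC 103 of them were lower and 31 higher in the KO-labelled libraries (median -0.09, or -0.14 with plain read totals and -0.16 under TPM, adjusted p = 0.0068, and 0.14 with an estimated correlation), and without AraC 33 and 59 (median 0.04, or 0.02 with plain read totals and under TPM, adjusted p = 0.72). The Rel homology family (9 genes, NFKB1, NFKB2 and RELB passing) and the ARID family (12 genes) had interaction medians of -0.32 and -0.17 (adjusted p = 3.4e-05 and 0.0011, and 0.0495 and 0.043 with an estimated correlation). Of the 9 Rel homology genes 4 are also in the NF-kB list, among them the 3 that passed, so this family is no separate evidence. On leaving out a library, the Rel homology and ARID families passed at an estimated correlation only without WT untreated replicate 3 or WT AraC replicate 3, and not without any other library (adjusted p from 0.050 to 0.11 and from 0.050 to 0.078), whereas the C2H2 family passed without each library. The MYB family (21 genes, median -0.11) and the SAND family (6 genes, -0.16) passed for the interaction at the preset correlation (adjusted p = 0.033 for both) and not at an estimated one (0.18 and 0.30), and the MYB median was -0.17 under TPM. The MYB call was lost without WT untreated replicate 3 (0.065), WT AraC replicate 3 (0.090) or KO untreated replicate 1 (0.061) or 2 (0.075), and the SAND call without WT untreated replicate 2 (0.056), WT AraC replicate 3 (0.097), KO untreated replicate 1 (0.069) or 3 (0.055) or KO AraC replicate 1 (0.066) or 2 (0.079). The 417 genes with a ZNF symbol, 348 of them in the C2H2 family, passed wherever that family did (with AraC not without KO AraC replicate 3, 0.051), with an interaction median of -0.12 (adjusted p = 5.2e-07, and 0.015 with an estimated correlation). The 29 genes of the HMG family were higher in 13 cases and lower in 2 in the KO-labelled libraries with AraC (median 0.11, adjusted p = 0.038, and 0.49 with an estimated correlation), with medians of 0.06 with plain read totals and 0.04 under TPM, and this call was lost without WT AraC replicate 2 (0.063) or KO AraC replicate 3 (0.051).

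Genes of chromosomes 13 and 8 were lower in the KO-labelled libraries (medians -0.49 and -0.28 without AraC, camera adjusted p over 23 chromosomes 0.0039 and 0.0015 with an estimated correlation), while AraC itself left the 2 chromosomes near 0, at -0.04 and -0.02 in WT. Windows of 15 to 26 protein-coding genes had medians from -0.66 to -0.19 on chromosome 13 and from -0.38 to -0.13 on chromosome 8. On the other chromosomes they ran from -0.14 to 0.18, all without AraC. With AraC the window of chromosome 13 from 27251309 to 36442882 had -0.08, within the -0.19 to 0.25 of the other chromosomes. Whether the shift is uneven along either chromosome was not tested. Over the 6 KO-labelled libraries and both chromosomes the median nearest to 0 was -0.25, which argues against a single library. The pattern was first seen on protein-coding genes (medians -0.51 and -0.28 without AraC). Averaged over the comparisons without and with AraC, the 149 genes of other biotypes on these chromosomes lay at -0.21 relative to 2693 such genes elsewhere. This was past the -0.2 set beforehand, but not without WT untreated replicate 1 (-0.197), WT AraC replicate 1 (-0.183), KO untreated replicate 1 (-0.177) or 2 (-0.182), or KO AraC replicate 1 (-0.171) or 3 (-0.181), so it does not decide the question. Fewer copies of these chromosomes, or of parts of them, in the KO-labelled line therefore stay an open hypothesis, from RNA alone.

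KLRF2, C4orf48, NPW, RTL8C and IQCC were at least 10-fold lower in the KO-labelled libraries and nearly silent there. The 171 tested genes within 1 Mb of them had a median KO against WT difference of -0.0029, averaged over the comparisons without and with AraC. Around the single genes the medians ran from -0.048 (NPW, 73 neighbours) to 0.14 (RTL8C, 12 neighbours). These values argue against a loss of most of the 1 Mb around these genes. A smaller lost segment with few neighbours would not move such medians and stays possible. Loss of the single genes, or of their activity, stays possible too. An effect of IKZF1 loss and a difference between cell clones unrelated to IKZF1 cannot be told apart for these 5 genes, because the labels name 1 knockout line.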
